A study of Mus musculus with 4 samples.

How the data were processed

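Poly(A) RNA from whole testes of mice at postnatal day 14 was sequenced by the study's authors in 4 libraries. According to the sample labels, 2 libraries came from Kctd19 heterozygotes (het) and 2 from Kctd19 knockouts (ko), all on a C57BL/6J background, and the replicates are biological. The deposited values are FPKM (fragments per kilobase of exon, scaled to the library's assigned reads), 1 value per gene symbol and library, per the file headers. CASAVA 1.9, STAR 2.6.1a, featureCounts, edgeR and the GRCm38 build are named in the submitters' processing notes, which state no role or setting for these tools in the form used here. The annotation release and whether strand was used in counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

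Each of the 4 tables held the same 55401 rows, of which 217 carried a symbol that occurs more than once and were kept as separate rows. Symbols were matched to the GENCODE M21 annotation of GRCm38 for position, gene type and total exon length, and 53177 rows (96.0%) matched. FPKM multiplied by exon length moved in steps, and 1 step was taken as 1 read. Among values of up to 20 reads, 99.1% or more in each library were whole numbers within a tolerance of 0.02. The steps gave 14638658 assigned reads for het replicate 1, 12155089 for het replicate 2, 19430364 for ko replicate 1 and 14573566 for ko replicate 2. A low value therefore has a wide counting error, and reads are given beside low values.

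The test planned for read counts was replaced, because the tables hold FPKM. Genes with a mean of at least 1 FPKM over the 4 libraries were kept (17905 genes), a pseudocount of 1 was added, and log2 values were fitted by genotype in limma 3.58.1 with an intensity trend, under R 4.3.3. A fold change on the log2(FPKM + 1) scale understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Before the data were examined, 23 gene lists, the test, the rule for named genes and a first set of alternatives were written down. The lists covered germ cell stages, meiotic functions, somatic and immune cell types, stress responses, mitochondrial transcripts and partners of Kctd19. The named genes were Kctd19, then up to 10 called genes per direction with the largest log2 fold change, whose ko libraries lay on the same side of both het libraries and whose symbol is not a model name. From each list came up to 4 called members by smallest p or, where none was called, up to 2 members as values only. The values of 1 gene that met this rule are not reported here.

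Lists were tested with limma's camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry's directional and mixed tests, each adjusted over the 23 lists by the Benjamini-Hochberg method. X-linked and Y-linked genes were tested in the same way as a separate pair of sets. The replicates differed by more than counting error, with a chi-square per gene of 6.41 between the het libraries (15769 genes with 20 or more reads in the pair) and 11.03 between the ko libraries (15917 genes), so each was counted as its own sample. Of the tested genes, 97.4% had a position in the annotation.

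The code was tested on simulated reads for 17169 genes at the real depths, with 200 genes changed. Of these, limma on FPKM recovered 25.5% at 2-fold, 80.0% at 4-fold and 84.5% at 8-fold, with 7, 16 and 18 false calls and 0 wrong signs. On the same simulated reads voom recovered 78.0%, 89.0% and 89.0%, with 12, 10 and 5 false calls. Camera called 5 of 100 unchanged lists of simulated reads at an unadjusted p under 0.05. The simulated genes were drawn independently of each other, so this count does not check camera on lists of correlated genes. Simulated genes of like expression also shared the same dispersion. Differences in variance between such genes were left out, and the recovery may not carry over to the real genes.

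Alternatives fixed in advance were a pseudocount of 0.1, no filter, the replicate number as a block, each library left out, a minimum change of 2-fold, an adjusted p under 0.01, an estimated correlation and fry. Alternatives added after seeing the data were limma voom on the whole reads, median-of-ratios scaling, upper-quartile scaling, quantile normalization and a restriction to protein-coding genes.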

Results

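Transcript levels were compared between 2 Kctd19 ko and 2 Kctd19 het testes of mice at postnatal day 14, an age at which the leading germ cells of the first spermatogenic wave are in meiotic prophase. The question was which transcripts differ in juvenile testes of the ko, Kctd19 being a protein expressed in meiotic germ cells. Assigned reads numbered 14638658 and 12155089 in the het libraries and 19430364 and 14573566 in the ko libraries. Across the 17905 genes tested, the het libraries correlated with each other at r = 0.966 and the ko libraries at r = 0.971, against 0.952 to 0.963 for het and ko pairs (correlations across genes, which are not independent replicates). Reads of mitochondrial genes made up 2.94% to 3.51% of each library.

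Kctd19 RNA remained in both ko libraries. Kctd19 (GRCm38 chromosome 8, 105382807 to 105413502) stood at 29.7 and 18.2 FPKM in the het libraries and at 12.8 and 15.6 FPKM in the ko libraries, or 24.0 ± 8.12 against 14.2 ± 1.99 (SD, n = 2 each). The log2 fold change was -0.69 (SE 0.25), which did not pass limma's test (Benjamini-Hochberg adjusted p = 0.529). It was -0.35 without het replicate 1 and -1.02 without het replicate 2, and did not pass in either. The labels do not say which part of the gene was deleted, and a value summed over all exons does not check a knockout that leaves most of the transcript in place. An exon of Kctd19 overlaps one of Plekhg4 in the annotation, and reads in that overlap cannot be told apart.

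Interferon response genes were higher in both ko libraries than in both het libraries. Limma called 37 genes higher in ko and 2 lower, among 877 higher and 790 lower at an unadjusted p under 0.05. Iigp1, an interferon-inducible GTPase (chromosome 18, 60376027 to 60392634), rose from 0.548 ± 0.0551 to 16.7 ± 0.170 FPKM (SD, n = 2), a log2 fold change of 3.52 (SE 0.10, limma with Benjamini-Hochberg adjusted p = 0.0134). Related GTPases rose with it: Irgm2 from 1.497 to 16.0 FPKM and Gbp2 from 1.81 to 16.8 FPKM in the group means. The chemokine Ccl8 rose from 3 reads in each het library to 121 and 90 reads in the ko libraries.

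Components of both antigen presentation pathways were among the 10 named genes with the largest increases. Cd74, the invariant chain of class II complexes, rose 11.0-fold, from 4.01 ± 0.197 to 44.0 ± 9.36 FPKM (SD, n = 2, log2 fold change 3.15, SE 0.16). The class II chains H2-Eb1 and H2-Aa rose 12.1-fold and 13.7-fold, to means of 14.4 and 9.42 FPKM. Tap1, a subunit of the peptide transporter of the class I pathway, rose 10.3-fold (log2 fold change 2.65, SE 0.11). Nlrc5, the transactivator of class I genes, rose from 0.187 to 7.33 FPKM, with 20 and 22 reads in the het libraries and 1011 and 1057 in the ko libraries. The limma Benjamini-Hochberg adjusted p of these 5 genes lay between 0.0171 and 0.0325. Mir5107, called with the largest log2 fold change (3.91, SE 0.30), is an annotated microRNA inside Cd74, and its reads cannot be told apart from those of Cd74. Class I genes belong to a family of near-identical copies, and the split of reads among H2 genes is uncertain.

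**Figure D1:**
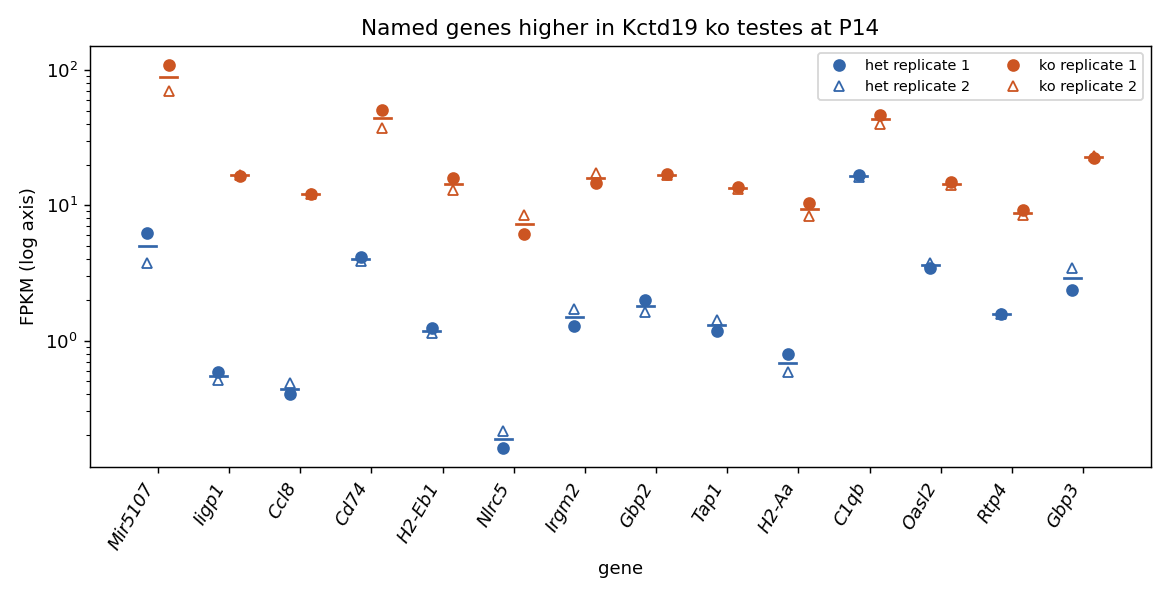
FPKM (log axis) of named genes called higher in ko, with 1 point per library (blue het, orange ko, filled replicate 1, open replicate 2) and a bar at the mean of each genotype. In every gene shown both ko points lie above both het points, as for Gbp3 at 2.36 and 3.43 FPKM in het and 22.4 and 23.1 FPKM in ko.

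In the interferon response list, limma on FPKM called 4 of 13 tested members higher and 0 lower, 9 were not called, and all 13 rose when adjusted over the list alone. Voom on whole reads called 12 of the 13 higher. Both ko libraries lay above both het libraries in all 13, an arrangement that chance gives in 16.7% of independent genes. The 37 genes called higher held 4 list members against 0.0269 expected (one-sided Fisher's exact test, p = 1.09e-08). Both comparisons assume independent genes, but the members are correlated, so neither measures the spread between animals. Gbp3 rose 7.85-fold, Rtp4 5.61-fold and the antiviral synthetase-like gene Oasl2 4.02-fold, each at a limma Benjamini-Hochberg adjusted p of 0.0238. The list's median log2 fold change was 1.65, and camera passed it (limma's camera, Benjamini-Hochberg adjusted p = 4.89e-22). With an estimated correlation of 0.54 between members, that call was lost (limma camera, Benjamini-Hochberg adjusted p = 0.679, unadjusted p = 0.0613), and fry's directional test gave an unadjusted p of 0.00485 (adjusted p = 0.111, Benjamini-Hochberg in limma). Fry's mixed test, for change in either direction, passed the list (limma, Benjamini-Hochberg adjusted p = 0.0309).

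Most macrophage markers moved with the interferon genes. Of 14 tested members, limma on FPKM called 3 higher and 0 lower, 11 were not called, and 11 rose when adjusted over the list alone. Voom on whole reads called 8 higher. The members called by limma on FPKM were Cd74, H2-Aa and the complement gene C1qb, which rose 2.64-fold, from 16.4 ± 0.376 to 43.2 ± 4.66 FPKM (SD, n = 2). Cd74 and H2-Aa are class II genes that interferon induces in several cell types. Csf1r, Cx3cr1 and Mrc1, named here after their values were seen, did not pass when adjusted over the list alone. Their log2 fold changes were 0.21, 0.29 and -0.03. The median log2 fold change was 1.01 and passed camera (limma, Benjamini-Hochberg adjusted p = 1.46e-15), a call lost with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p = 0.679).

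The immediate early and heat shock list lay higher in ko by a median log2 fold change of 0.29 (limma camera, Benjamini-Hochberg adjusted p = 0.000477), and with an estimated correlation it did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.679). It did not pass fry's directional test but passed the mixed test (limma, Benjamini-Hochberg adjusted p = 0.192 and 0.0101). None of its 16 tested members was called over all genes by limma on FPKM, 7 were higher at an unadjusted p under 0.05, and voom on whole reads called 1, Hspb1. When adjusted over the list alone, 2 rose, namely Hspb1 (20.7 and 23.9 FPKM in het, 34.9 and 32.5 FPKM in ko) and Junb (4.95 and 4.05 against 7.25 and 7.62 FPKM). The members of this list respond to tissue handling as well as to signalling.

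Of the 2 genes called lower, Zfp820, a zinc finger gene in a cluster of such genes (chromosome 17, 21816885 to 21845772), fell from 20.7 and 14.01 FPKM to 1.92 and 2.09 FPKM (log2 fold change -2.59, SE 0.20, limma with Benjamini-Hochberg adjusted p = 0.0375). The other was Gm10060, a processed pseudogene named here after its values were seen, with 18 and 16 reads in het and 10 and 7 reads in ko, so its level rests on few reads.

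These counts of calls were not kept in every setting. Without het replicate 1, het replicate 2, ko replicate 1 or ko replicate 2 limma called 0 genes, with 563 to 986 higher and 498 to 1034 lower at an unadjusted p under 0.05, and without the filter it also called 0, while voom on whole reads called 133 higher and 107 lower, including all 37 higher genes.

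Lists of pachytene spermatocytes, the piRNA pathway and the flagellum passed camera as lower in ko at the preset correlation only. With estimated correlations of 0.59, 0.63 and 0.85 all 3 calls were lost (limma camera, Benjamini-Hochberg adjusted p = 0.738 for each), and fry's directional test passed none of the 3 (limma, Benjamini-Hochberg adjusted p = 0.603, 0.507 and 0.507). Limma on FPKM called 0 of their members over all genes, with 10 members of the cilium list, 5 of the piRNA list and 8 of the pachytene list lower at an unadjusted p under 0.05. Voom on whole reads called 7, 3 and 4 of them lower, among them Cfap65, Ccdc39, Piwil1, Rnf17 and Ldhc. In the cilium and flagellum list all 21 tested members had a log2 fold change below 0, with a median of -0.52 (limma camera, Benjamini-Hochberg adjusted p = 2.28e-10). Cfap65 and Ccdc39, which passed when adjusted over the list alone, stood at 9.22 and 5.01 FPKM in het against 0.777 and 1.40 FPKM in ko, and at 11.8 and 9.74 against 6.38 and 6.78 FPKM. The piRNA list had a median of -0.26 over 18 members (limma camera, Benjamini-Hochberg adjusted p = 1.47e-06). Piwil1, the PIWI protein of pachytene spermatocytes, was its 1 member past the threshold adjusted over the list alone, at 28.1 and 14.3 FPKM in het and 3.65 and 5.01 FPKM in ko, and Rnf17 stood at 31.5 and 26.4 against 19.8 and 21.04 FPKM. The list of pachytene regulators and markers had a median of -0.32 over 26 members (limma camera, Benjamini-Hochberg adjusted p = 1.92e-06), 0 of which passed when adjusted over the list alone. In it Ldhc, the lactate dehydrogenase of male germ cells, stood at 78.0 and 30.7 FPKM in het and 11.7 and 10.6 FPKM in ko. The het libraries differed in the same genes: without het replicate 1 the medians were -0.34, -0.14 and -0.11, and without het replicate 2 they were -0.76, -0.44 and -0.56. Without ko replicate 2 the piRNA median was -0.36.

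**Figure D2:**
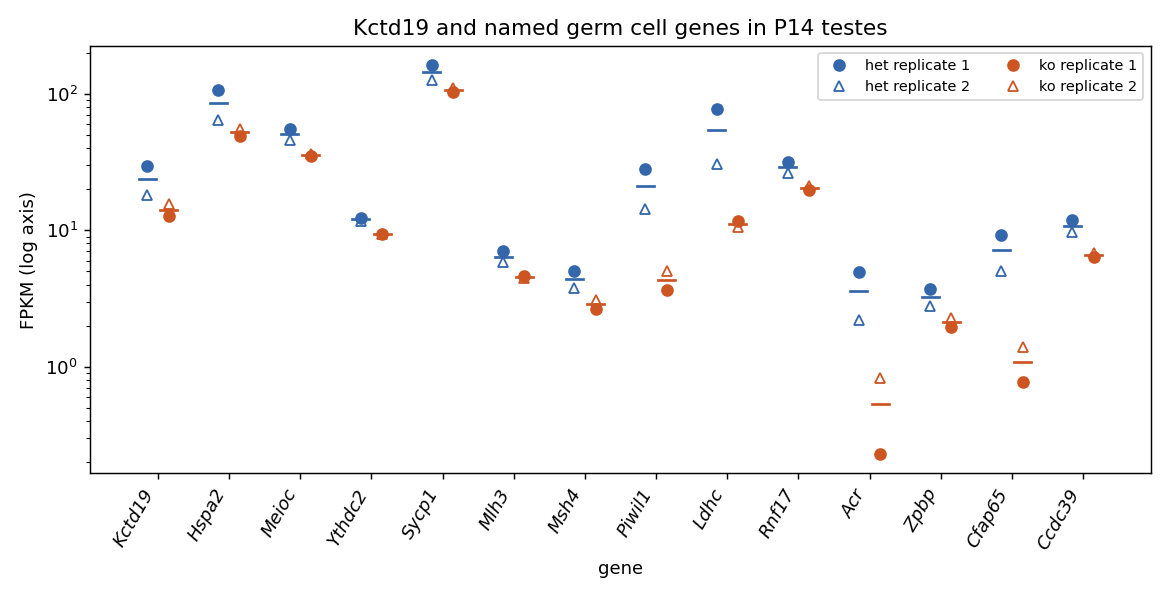
FPKM (log axis) of Kctd19 and of named germ cell genes, with 1 point per library (blue het, orange ko, filled replicate 1, open replicate 2) and a bar at the mean of each genotype. The ko points of Piwil1 (3.65 and 5.01 FPKM) lie below both het points, which themselves lie at 28.1 and 14.3 FPKM.

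Among lists of earlier meiosis, the crossover list had a median of -0.19 over 16 members (limma camera, Benjamini-Hochberg adjusted p = 0.0298, and adjusted p = 0.679 with an estimated correlation). Mlh3 stood at 7.00 and 5.82 against 4.599 and 4.49 FPKM and Msh4 at 5.03 and 3.75 against 2.66 and 3.09 FPKM. This list did not pass without het replicate 1 (median -0.08) or without ko replicate 1 (median -0.08). The lists of the synaptonemal complex and cohesin (median -0.15, 18 members) and of meiotic entry and recombination (median -0.02, 24 members) did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.0901 and 0.358). Among their members Sycp1 stood at 162 and 126 FPKM in het and 104 and 110 FPKM in ko, Rec8 at 12.5 and 13.1 against 14.9 and 15.01 FPKM, Meioc at 54.9 and 45.9 against 35.2 and 36.3 FPKM, and Ythdc2 at 12.4 and 11.7 against 9.39 and 9.34 FPKM. Without het replicate 2 and without ko replicate 2 the synaptonemal list (medians -0.26 and -0.16) and the meiotic entry list (medians -0.13 and -0.12) passed. Without het replicate 1 their medians were -0.045 and 0.029, without ko replicate 1 they were -0.13 and 0.021, and neither passed. The synaptonemal list also passed with voom on whole reads, after quantile normalization and with protein-coding genes only. Limma on FPKM called 0 members of these 3 lists, over all genes or adjusted over the list alone, and voom on whole reads called 1 lower, Meioc.

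Lists for division (median 0.05, 23 members), round spermatids and acrosome (median -0.23, mean 0.12, 15 members), testis histone variants (median 0.07, mean -0.0032, 7 members) and sex-linked germ cell genes (median 0.02, 20 members) did not pass camera (limma, Benjamini-Hochberg adjusted p = 0.673, 0.137, 0.726 and 0.807). The division list's camera direction was down while its median was above 0, and the round spermatid list passed without het replicate 2 (median -0.19) and with voom on whole reads (median -0.28). Without het replicate 1 the round spermatid median was -0.040, and the list did not pass. In that list Prm1 and Tnp1, named after their values were seen, stood at 15.5 and 12.4 FPKM in ko replicate 1 and at most at 0.481 and 0.938 FPKM in the other libraries. Examples were Sgo2a (10.2 and 8.75 against 7.41 and 7.45 FPKM), Nek2 (25.7 and 18.7 against 15.5 and 15.6 FPKM), Acr (4.97 and 2.21 against 0.230 and 0.832 FPKM), Zpbp (3.73 and 2.79 against 1.96 and 2.28 FPKM), Nr0b1 (29.6 and 28.2 against 41.7 and 35.4 FPKM) and Zfy2 (3.87 and 3.20 against 2.17 and 2.32 FPKM). Of the histone variants, H2bc1 stood at 13.0 and 12.4 FPKM in het and 6.17 and 11.6 FPKM in ko, and H3f4 at 7.81 and 5.80 against 8.01 and 8.51 FPKM. Limma on FPKM called 0 members of these 4 lists, over all genes or adjusted over the list alone, and voom on whole reads called 1 lower, Acr.

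The 7 genes listed as partners of Kctd19, among them its complex partner Zfp541, did not pass as a list (median 0.04, mean -0.06, camera direction down; limma camera, Benjamini-Hochberg adjusted p = 0.799). Zfp541 stood at 14.995 and 12.4 FPKM in het and 13.8 and 17.4 FPKM in ko, and the germ cell chaperone Hspa2 at 107 and 63.8 against 49.2 and 55.2 FPKM.

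Differentiating spermatogonia markers lay higher by a median of 0.16 over 14 members (limma camera, Benjamini-Hochberg adjusted p = 0.0183, and adjusted p = 0.738 with an estimated correlation). Sohlh2 stood at 20.6 and 17.1 FPKM in het and 24.9 and 25.0 FPKM in ko, and Crabp1 at 29.4 and 42.5 against 50.4 and 49.4 FPKM. The call was lost without het replicate 1 (median 0.11), without ko replicate 1 (median 0.11) and after quantile normalization (median 0.12). The undifferentiated list had a median of 0.14 over 13 members and did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.0931), though it did without het replicate 2 (median 0.28), with no filter (median 0.13) and with voom on whole reads (median 0.19). Without het replicate 1 its median was 0.052, and it did not pass. In it Neurog3 stood at 1.51 and 1.67 against 2.64 and 2.42 FPKM and Uchl1 at 79.4 and 103 against 126 and 108 FPKM.

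**Figure D3:**
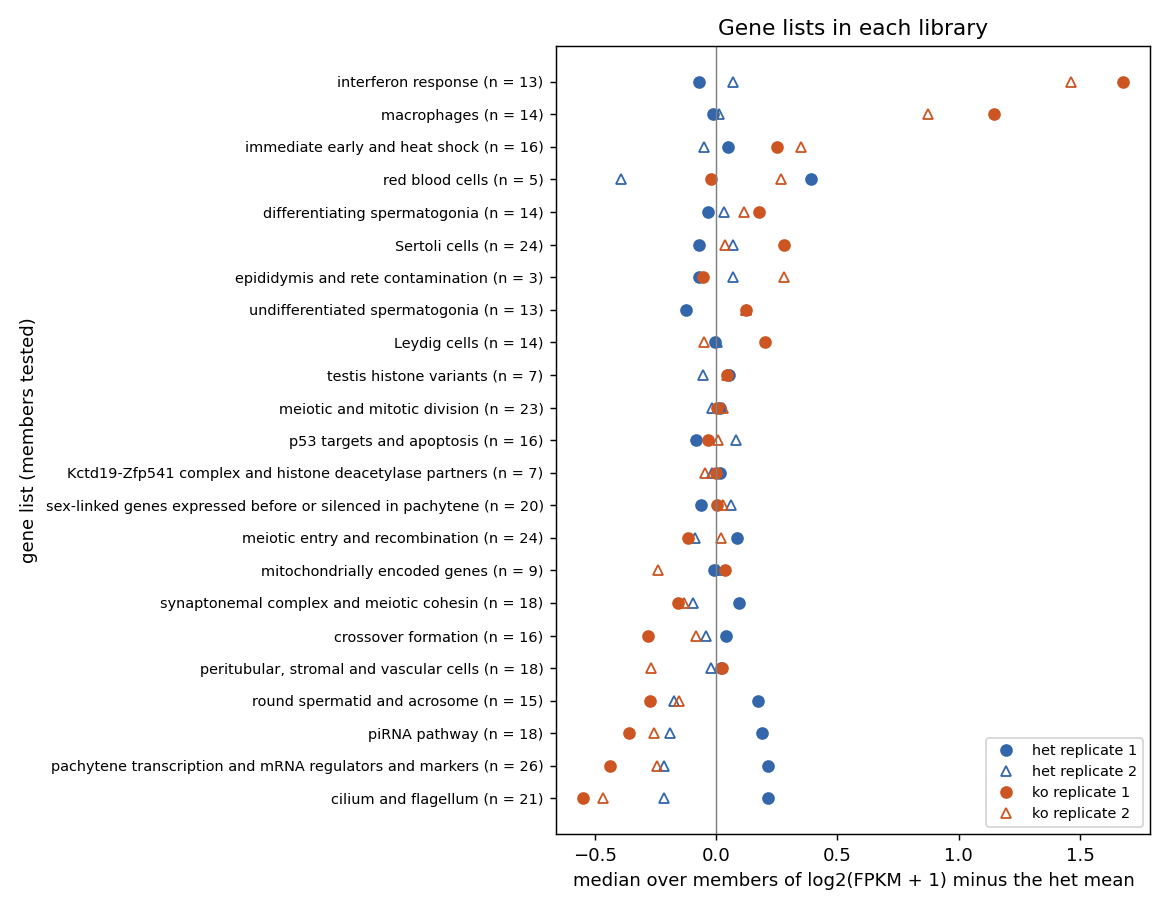
Median over the tested members of each list of log2(FPKM + 1) minus the mean of the het libraries, with 1 point per library (blue het, orange ko, filled replicate 1, open replicate 2) and lists ordered by their median log2 fold change. The interferon response list lies at 1.68 and 1.46 in the ko libraries and the cilium and flagellum list at -0.55 and -0.46, while the het libraries lie at 0.21 and -0.21 for the latter.

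Among somatic cells, Sertoli markers lay higher by a median of 0.16 over 24 members and peritubular, stromal and vascular markers lower by a median of -0.19 over 18 members (limma camera, Benjamini-Hochberg adjusted p = 0.01005 for each), and neither passed with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p = 0.820 for each). Clu stood at 398 and 500 FPKM in het and 657 and 561 FPKM in ko, and Cst12 at 302 and 399 against 505 and 432 FPKM. Nr2f2 stood at 10.5 and 11.3 against 9.31 and 8.46 FPKM and Cdh5 at 8.52 and 9.02 against 7.51 and 7.09 FPKM. The Sertoli call was lost without het replicate 1 (median 0.07), without ko replicate 1 (median 0.04) and after quantile normalization (median 0.11), and without ko replicate 2 the median was 0.28. The stromal call was lost without het replicate 1 (median -0.11) and without ko replicate 2, where the median turned to 0.03. None of the members of these lists was called, over all genes or adjusted over the list alone.

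The remaining lists did not pass camera. Leydig cells had a median of 0.09 over 14 members, red blood cells 0.17 over 5, epididymis and rete 0.14 over 3, p53 targets 0.05 over 16 and mitochondrially encoded genes -0.09 over 9 (limma camera, Benjamini-Hochberg adjusted p = 0.246, 0.556, 0.616, 0.579 and 0.220). Red blood cell genes passed without het replicate 1 (median 0.61), Leydig genes without ko replicate 2 (median 0.20) and mitochondrial genes without ko replicate 1 (median -0.24). Limma and voom called 0 of their members, over all genes or, for limma, adjusted over the list alone. Their members with the smallest p were Scarb1 (19.9 and 18.6 against 22.95 and 22.4 FPKM) and Lhcgr (2.44 and 4.80 against 2.44 and 1.53 FPKM), Hba-a2 (1.54 and 0.617 against 1.85 and 1.44 FPKM) and Hbb-bs (54.3 and 31.2 against 46.0 and 57.7 FPKM), Cst11 (2.999 and 2.14 against 2.34 and 3.57 FPKM) and Cst8 (6.57 and 7.33 against 11.1 and 5.71 FPKM), Bax (30.3 and 30.6 against 39.8 and 36.4 FPKM) and Gadd45a (11.3 and 10.2 against 12.7 and 12.4 FPKM), and mt-Atp8 (3.01 and 2.42 against 2.27 and 0.673 FPKM) and mt-Nd5 (2043 and 2114 against 2021 and 1529 FPKM), het before ko in each.

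Genes of the sex chromosomes showed no shift past the test. The median log2 fold change was 0.01 over 651 X-linked genes and -0.11 over 11 Y-linked genes (limma camera, Benjamini-Hochberg adjusted p = 0.437 and 0.349, and adjusted p = 0.857 and 0.581 with an estimated correlation). Without het replicate 2 the X-linked set passed (median 0.073), and its median was -0.030 without het replicate 1 and -0.0237 without ko replicate 1. Limma called 0 genes of either chromosome, with 40 X-linked genes and 1 Y-linked gene at an unadjusted p under 0.05, and voom on whole reads called 2 X-linked genes and 0 Y-linked genes.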

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

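Alternatives other than voom on whole reads, the scalings, quantile normalization and protein-coding genes only were chosen before the data were examined. The planned variants with edgeR, DESeq2, their scalings and a stricter read filter were not run, because the tables hold FPKM. Higher and lower calls stayed within 1.5 times of 37 and 2 with the other pseudocount (34 and 3, of which 33 and 2 were shared), the scalings, quantile normalization and a 2-fold minimum. Leaving out any 1 library left 0 and 0 calls (range 0 to 0), from fits with 1 residual degree of freedom in which the lone library of a genotype is assumed to vary like the others. Without the filter 37429 genes were tested and limma called 0 and 0, with 1434 higher and 1206 lower at an unadjusted p under 0.05, and at an adjusted p under 0.01 it called 0 and 0; the cause was not tested. Protein-coding genes only gave 94 and 14 calls from fewer tests (12796 genes), and voom gave 133 and 107, with 37 and 1 shared. With the replicate number as a block, 15 and 0 genes were called, 14 of the 37 among them; deviations of same-numbered libraries correlated at -0.03 across genes, and the labels name no shared litter or batch, so the libraries are not treated as pairs, and the block ended or made no list call.

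The Kctd19 log2 fold change ran from -1.02 to -0.35 and passed in none of the 12 refits. Of 23 lists, 10 passed camera, 7 to 14 with a library left out, 0 with an estimated correlation and 0 with fry's directional test (adjusted by Benjamini-Hochberg in limma), where 2 residual degrees of freedom leave the correlation poorly known; fry's mixed test passed 2 lists, interferon response and immediate early and heat shock. The X-linked median ran from -0.030 to 0.073 with a library left out, reversing without het replicate 1 (-0.030) and ko replicate 1 (-0.0237) and passing without het replicate 2 (0.073), and the Y-linked median was 0.035 with no filter. With a library left out, medians crossed 0 for Kctd19 partners (-0.048 to 0.053; -0.0018 with protein-coding genes only), meiotic entry (-0.134 to 0.029), division (-0.0029 to 0.050), sex-linked genes (-0.022 to 0.102; -0.0044 after quantile normalization), Leydig cells (-0.050 to 0.203), stromal cells (-0.267 to 0.026), red blood cells (-0.151 to 0.606), epididymis (-0.055 to 0.281), p53 targets (-0.034 to 0.163) and mitochondrial genes (-0.239 to 0.036), and log2 fold changes did so for Hbb-bs (-0.076 to 0.707), Cst11 (-0.084 to 0.367) and Cst8 (-0.242 to 0.608). The round spermatid median was 0.039 with no filter. Of all other refits of list medians, 234 kept direction and side of the threshold, 15 came to pass and 9 no longer passed; for named genes these were 578, 10 and 86. At the depth of these libraries limma on FPKM recovered 25.5% of simulated 2-fold changes and voom 78.0%. In the simulation the limit at this size of change thus lay in part in the test and not in the depth alone. Whether this holds for the real genes was not tested, because simulated genes of like expression shared the same dispersion.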

Other observations

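The gene groups of this part, and the tests other than that of late spermatid genes, were chosen after the results were seen, and the test of late spermatid genes was written down before its values were read. A comparison with the range of the other libraries was added to it after the values were seen. Among the gene groups, 10 of 23 class I antigen presentation genes were called higher in ko (median log2 fold change 1.27), 7 of 12 tested interferon-inducible GTPases (median 2.29) and 3 of 7 tested class II genes (median 2.10). Limma's camera with an estimated correlation gave unadjusted p-values of 0.0517, 0.0139 and 0.0446, and none of these values is independent evidence because called genes had prompted the groups. B2m, the light chain of class I complexes, went from 89.3 and 108 FPKM in het to 581 and 464 FPKM in ko. Psmb10, an immunoproteasome subunit called higher (6.93 and 6.85 against 18.4 and 17.7 FPKM), lies at 105935735 to 105938444 on chromosome 8, within 1 Mb of Kctd19. Nlrc5 also lies on chromosome 8, farther from Kctd19, at 94434356 to 94527272. Genes of T and natural killer cells held 11.1 and 9.13 CPM (pooled reads scaled to the library total) in het and 15.2 and 17.8 in ko, and the B cell gene Ighm stood at 1.81 and 2.22 against 6.00 and 5.24 FPKM (limma, Benjamini-Hochberg adjusted p = 0.134).

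Next to Zfp820 on chromosome 17, Gm9818 (21808186 to 21808444) stood at 9.38 and 7.42 FPKM in het and 0 and 1.61 FPKM in ko, and did not pass (limma, Benjamini-Hochberg adjusted p = 0.306). The log2 fold changes of the other tested genes within 1 Mb of Zfp820 ran from -0.92 (Gm26384) to 0.19 (Ppp2r1a). None of those genes was called.

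The rise of interferon-response genes in both ko libraries was weighed against 3 other explanations. For a larger share of macrophages as the whole source, 17 list members had a median log2 ratio by CPM of 2.01. The 13 macrophage markers without the inducible class II genes had 0.77, a difference of 1.24 (two-sided permutation test over genes, p = 0.000160). These medians argue against that source if the markers track the share of macrophages, though more macrophages could account for a part. The p-value treats correlated genes as independent (estimated correlations 0.54 and 0.61 in the 2 tested lists) and leaves out the spread between animals. Members needed 20 reads over the 4 libraries, which ko reads alone could supply. A strain haplotype of the histocompatibility region on chromosome 17 acting on its own genes could by definition account for no called gene elsewhere. Of the genes called higher, 24.3% (9 of 37) lie on chromosome 17. That 0 of the 17 list members lie there was fixed when the list was written and tests nothing. For the 9 called genes on chromosome 17 this haplotype stays open. Their median log2 ratio exceeded that of the other called genes by 0.18 (two-sided permutation test over genes, p = 0.873), which decides nothing. An infection or housing exposure shared by the ko animals cannot be told apart from the genotype, since 0 of the labelled characteristics other than genotype vary, so an effect of losing Kctd19 is an untested hypothesis.

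The lower pachytene, piRNA and cilium genes may reflect a spread in the progress of germ cells between animals as well as the genotype: over 63 members, het replicate 1 exceeded het replicate 2 by a median of 0.41 and the het mean exceeded the ko mean by 0.34, a ratio of 1.19, in a comparison that could have shown near-equal het libraries. The ko libraries differed by a median of -0.07 (replicate 1 minus replicate 2), and het replicate 2, the lower het library, still exceeded the ko mean by 0.16. Both ko libraries lay below both het libraries in 44 of the 63 members (69.8%, against 16.7% by chance for independent genes), a share that tests nothing here because the members are correlated and the lists were picked as lower in ko. Dilution by a larger share of somatic cells was not settled by the somatic lists. Sertoli and stromal markers moved apart by 0.35 in their medians (two-sided permutation test over genes, p = 2.00e-05), which goes against somatic lists raised alike. That p-value treats correlated genes as independent. The stromal fall came from ko replicate 2 (median -0.27, against 0.03 in ko replicate 1). The Sertoli rise came mainly from ko replicate 1 (median 0.28, against 0.04 in ko replicate 2). A larger share of Sertoli cells alone could not be excluded by this comparison. Dilution should, however, lower germ cell genes of every stage alike. The differentiating spermatogonia list lay at 0.18 and 0.11 in the ko libraries, above both het libraries (-0.03 and 0.03). The meiotic entry list lay at -0.12 and 0.02 in ko. These medians argue against dilution as the whole source of the lower genes, though it could account for a part. Slower germ cell progress in ko as an effect of the genotype stays open and was not tested.

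In ko replicate 1 alone, the protamine and transition protein genes of elongating spermatids were present: Prm1, Tnp1, Prm2 and Tnp2 had 172, 105, 99 and 60 reads, against 0 to 6 in each other library. If RNA or reads from a mature testis had entered that library, other late spermatid genes should be raised too, and 15 such genes gave a pooled 46.7 CPM in it (exact Poisson 95% interval 43.7 to 49.8), against 40.1 (36.9 to 43.5), 31.8 and 32.7 CPM in het replicate 1, het replicate 2 and ko replicate 2. The planned criterion, intervals that do not overlap, was met, but such intervals cover counting error only and leave out the spread between animals, and the gap of 6.58 CPM to the next library was smaller than the range of 8.26 CPM among the other 3, so the test leaves the source open. Of these reads 587 came from Oaz3, present in all 4 libraries, and without it, a choice made after seeing the values, the pool was 16.5 CPM against at most 3.96 CPM. At postnatal day 14 the leading germ cells are in meiotic prophase. The pachytene and cilium lists also lay lowest in ko replicate 1 (medians -0.44 and -0.55, against -0.24 and -0.46 in ko replicate 2). Both points argue against late germ cells in that animal, if its labelled age is right. RNA or reads from a mature testis stay open as the source, and no biological explanation was tested.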
